A study of Mus musculus with 12 samples.

How the data were processed

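Expression arrays of the mouse JE131 cell line (DN3 cells, grown in RPMI1640 with fetal bovine serum) were compared in 4 groups of 3 arrays, which are untransduced cells and cells 1, 2 and 3 days after transduction with a retrovirus carrying HA-tagged wild-type mouse Ikaros. Per the labels' protocols, total RNA was extracted with a column kit, biotin labelled and hybridized at a core facility. The authors deposited 1 table of log2 values with 45101 probe sets for the 12 arrays, and the log2 unit was taken from the values, which ran from 2.05 to 15.07, since no header states it. The normalization that the authors used, and the software, are not given in the sources used here, and the genome build named in the submitters' processing notes is mm9. No coordinates are reported. Array medians of 5.62 to 5.74 and nearly equal quartiles show that the deposited arrays had been brought to a common scale, which can hide a change shared by most genes.

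The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, and 64 probe sets on the array were controls. No symbol was updated through its Entrez gene ID. Probe sets with several symbols, with none, and controls were left out of the tests. For each gene the probe set with the highest mean over the 12 arrays was tested, which gave 18193 genes, and 9010 genes had over 1 probe set. The control probe sets were read separately: hybridization controls, and the 3' and 5' probe sets of actin, Gapdh and the transferrin receptor. No column of the table was left unused.

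Groups came from the labels. limma 3.58.1 (R 4.3.3) fitted 4 group means to all 12 arrays (8 residual degrees of freedom) with lmFit and eBayes, and 6 contrasts and a moderated F test were read from this fit. p-values were adjusted by Benjamini-Hochberg over the 18193 genes, with a threshold of 0.05, and are two-sided. A log2 change is later minus earlier, and errors of changes are limma's standard errors. The replicate numbers in the labels are not stated to mark a shared day, so no replicate block was used. The steps were tested on simulated data built on the comparison of 3 days with untransduced cells: of genes changed 1.5-fold 92 of 100 were called, of genes changed 2-fold 100 of 100, and of 17971 unchanged genes 9.

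The list tests used limma's camera with a preset correlation of 0.01, adjusted over the 29 lists within a comparison, with camera on correlations estimated per list and fry beside it. The lists were the Ikaros family, the T cell receptor complex and proximal signalling, DN to DP transition markers, DN1 to DN3 stage markers, Notch targets, Myc and ribosome biogenesis, DNA replication and G1/S, G2/M and mitosis, cell cycle inhibitors and quiescence, glycolysis, cholesterol biosynthesis, amino acid and unfolded protein stress (Atf4, Xbp1), oxidative phosphorylation, interferon, NF-kB, p53 targets and apoptosis, the Bcl2 family, PI3K regulators, Jak and Stat signalling, T lineage transcription factors, chromatin remodelling and NuRD subunits, adhesion and homing, and replication dependent histones. Markers of B cells, myeloid cells, NK cells, erythroid cells, stem and progenitor cells, and fibroblasts or packaging cells stood for other cell types. A gene can stand in more than 1 list. Cd2, Cd4, Cd5, Cd8a, Cd8b1, Cd28 and Themis stood in both the T cell receptor and the DN to DP list, so results of these lists are not independent.

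The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the Ikaros family, the 12 largest rises and falls on each day against untransduced cells (adjusted p under 0.05 and arrays that do not overlap; 5 and 5 between successive days), the 4 members of each list with the largest change at 3 days, and any member of the lists on the DN to DP transition, the DN1 to DN3 stage, Notch, the T cell receptor, T lineage factors, cell cycle inhibitors and Myc. Predicted genes with no symbol of their own were passed over among the largest changes. For genes named as largest changes, arrays that do not overlap were thus a condition of their choice and no result. The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, only the arrays of the 2 groups compared, an intensity trend with a robust prior, array weights, the mean over a gene's probe sets, every probe set, an adjusted p under 0.01, a 2-fold minimum, an unmoderated 2-group test, a replicate block, estimated correlations for the lists, and each array left out in turn. Chosen after the data were seen were the removal of probe sets that can match several transcripts, the other Ikzf1 probe set, and estimated correlations without third-day array 1. Overlaps between comparisons that share the untransduced arrays were set beside 50 simulations of unchanged groups. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.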

Results

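Gene expression was measured on arrays in JE131, a mouse cell line of DN3 cells, which are T cell precursors at a stage before the coreceptors CD4 and CD8 appear (double negative, DN). The cells were taken without transduction or 1, 2 or 3 days after transduction with a retrovirus carrying HA-tagged wild-type mouse Ikaros, the zinc finger transcription factor of lymphoid cells that Ikzf1 encodes. Each of the 4 groups had 3 arrays, 12 in all, and the values are log2 signals of probe sets. The series concerns tumor suppression by Ikaros and the regulation of chromatin, and the 4 groups ask how expression differs on successive days after Ikaros was delivered. The labels describe neither cells given an empty retrovirus nor untransduced cells kept for the same days, so Ikaros, the transduction itself and time in culture cannot be told apart in any comparison here. They do not say that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 3 arrays per group, their number limits the precision: the median standard error of a log2 change was 0.1 over 18193 genes. Array medians ran from 5.62 to 5.74, and the correlation between arrays of one group from 0.994 to 0.998.

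The delivered gene was read by 2 probe sets that gave different answers. In the dimmer probe set Ikzf1 rose on each day, with log2 changes against untransduced cells of 0.96 ± 0.14 at 1 day, 0.66 ± 0.14 at 2 days and 1.24 ± 0.14 at 3 days (SE, n = 3 arrays per group). The adjusted p-values from limma over every probe set were 0.000402, 0.00175 and 1.38e-05. On single arrays this probe set read 6.02, 6.31 and 6.32 in untransduced cells and 7.42, 7.19 and 6.90 at 1 day. It read 6.82, 7.10 and 6.71 at 2 days and 7.48, 7.35 and 7.52 at 3 days. Every transduced array thus lay above every untransduced array. The brighter probe set, which stands for Ikzf1 in the test over genes, read 8.06 ± 0.345 in untransduced cells (SD, n = 3) and 8.05 ± 0.189, 8.75 ± 0.179 and 7.93 ± 0.092 on the 3 days. Its change passed limma's threshold only at 2 days (0.69 ± 0.15, adjusted p = 0.00255). The values were -0.01 ± 0.15 (adjusted p = 0.969) at 1 day and -0.13 ± 0.15 (adjusted p = 0.627) at 3 days. An unmoderated 2-group test did not call the change at 2 days (adjusted p = 0.1). The mean of both probe sets was 0.472 at 1 day (adjusted p = 0.0103) and 0.553 at 3 days (adjusted p = 0.00209). Which part of the Ikzf1 transcript each probe set reads, and whether the retroviral transcript holds it, is not used here, so neither probe set by itself checks the labels. As a setting beside the tested one, the dimmer probe set was chosen after the data were seen. Its rises at 1 and 2 days cross the array division described below, while that at 3 days does not. Of the other Ikaros family members, Ikzf3 (Aiolos) rose at 3 days by 0.82 ± 0.09 (adjusted p = 1.09e-05; 0.46 as the mean over its probe sets). Ikzf2 (Helios) was higher at 2 days (1.12 ± 0.19, adjusted p = 0.000329) and lower at 3 days (-0.82 ± 0.19, adjusted p = 0.00484). The other 2 probe sets of Ikzf2 read -1.63 (adjusted p = 8.56e-06) and 0.015 at 1 day, where the one used read -0.09. They read -0.73 and 0.57 at 2 days and -0.78 and -0.01 (adjusted p = 0.984) at 3 days. Its calls at 1 and at 3 days and its direction at 2 days thus depended on the probe set. The one used did not pass the unmoderated 2-group test at 3 days. Neither Ikzf4 nor Ikzf5 passed limma's threshold on any day against untransduced cells.

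**Figure D1:**
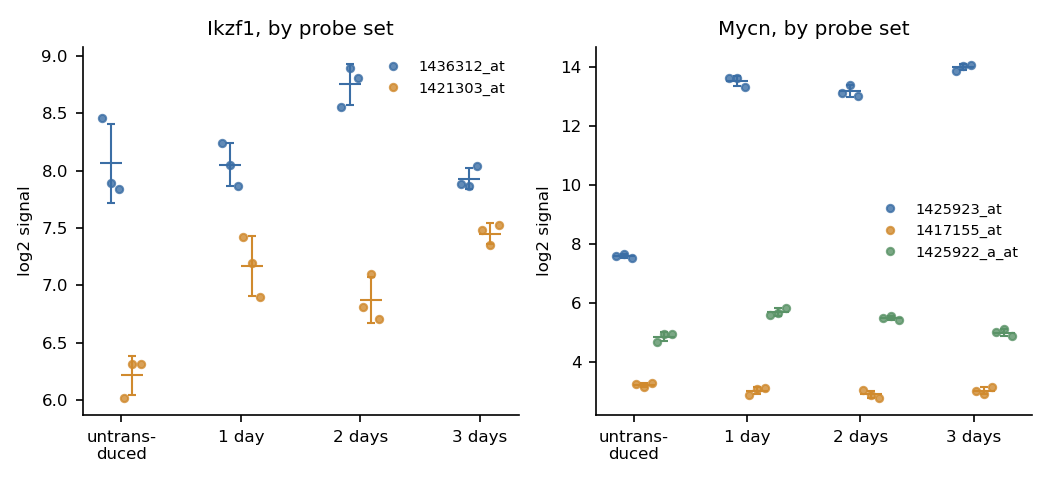
The log2 value of each probe set of Ikzf1 and of Mycn on every array (points), by group, with the group mean (line) and SD (bar, n = 3). Ikzf1 reads higher on all transduced arrays in one probe set (6.22 in untransduced cells and 7.45 at 3 days) and not in the other, and a single Mycn probe set goes from 7.60 to 13.54, 13.19 and 14.01.

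The arrays fell on 2 sides in a measure that involves no cell. The bacterial transcripts added at hybridization averaged 9.77 ± 0.117 in untransduced cells and 9.82 ± 0.125 at 3 days, against 11.09 ± 0.089 at 1 day and 11.02 ± 0.076 at 2 days (log2, SD, n = 3 arrays each). No array lay between the sides. Malat1, a long nuclear RNA, followed the same division, at 13.08 and 13.35 on one side and 11.32 and 11.36 on the other. The 3 days against untransduced and the 2 days against 1 day comparisons therefore stay within a side, whereas the 4 others cross it. Every group lies wholly on one side, so no term for the side can be fitted beside the groups, and in the 4 crossing comparisons it cannot be told apart from time. A contrast of days 1 and 2 against untransduced and day 3 called 7027 genes, while the other pairings of the groups called 3811 (days 1 and 3) and 5347 (days 2 and 3). The at least 2-fold changes among them numbered 119 (days 1 and 2), 107 (days 1 and 3) and 190 (days 2 and 3). Signal at the 3' end of the transferrin receptor transcript exceeded that at its 5' end by 0.32 ± 0.127 in untransduced cells, 0.723 ± 0.388 at 1 day, 1.42 ± 0.171 at 2 days and 0.904 ± 0.281 at 3 days. This measure of RNA integrity and labelling was thus largest at 2 days. The matching differences were 0.507, 0.599, 0.732 and 0.475 for actin and between -0.147 and -0.088 for Gapdh.

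**Figure D2:**
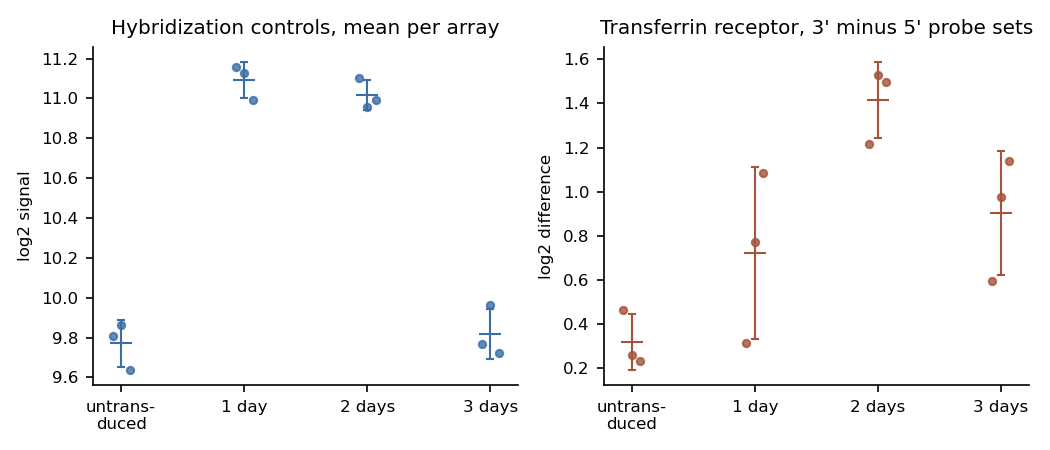
Mean log2 signal of the hybridization controls and the 3' minus 5' log2 difference of the transferrin receptor control on each array (points), by group, with the group mean (line) and SD (bar, n = 3). The hybridization controls are near 9.8 in untransduced cells and at 3 days and near 11 at 1 and 2 days, and the transferrin receptor difference is largest at 2 days.

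After 3 days with Ikaros, cells expressed more of the genes that mark passage to the CD4 and CD8 double positive (DP) stage. The transferrin receptor's 3' to 5' difference separated these groups too (0.593 to 1.14 at 3 days, 0.234 to 0.466 in untransduced cells), while that of actin did not (0.461 to 0.483 and 0.481 to 0.536). Cd8b1, a chain of the CD8 coreceptor, rose by 2.67 ± 0.12 (adjusted p = 1.91e-09), from 10.33 to 13.01, and Cd4 by 1.89 ± 0.14 (adjusted p = 2.18e-07), from 7.13 to 9.02 (log2, SE, n = 3 arrays per group). Cd5, a brake on T cell receptor signalling, rose by 2.65 ± 0.20 (adjusted p = 2.58e-07), and Cd2 by 3.48 ± 0.29 (adjusted p = 7.84e-07). The transcription factor Ets2 rose by 1.26 ± 0.09 (adjusted p = 2.26e-07). Of the 25 measured DN to DP transition genes 19 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.79. camera gave this list an adjusted p of 4.22e-12 with the preset correlation and 0.24 with an estimated correlation. In the list of the T cell receptor complex and its proximal signalling, 16 of 23 genes rose and 3 fell (18 and 4 adjusted over the list alone), with a median of 0.68. The list had a camera adjusted p = 7.5e-09, and adjusted p = 0.266 with an estimated correlation. It included the kinase Txk (2.87 ± 0.16, adjusted p = 1.81e-08), the adaptors Sit1 (2.25 ± 0.08, adjusted p = 2.84e-10) and Skap1 (1.36 ± 0.09, adjusted p = 6.11e-08) and the scaffold Lat (0.68 ± 0.07, adjusted p = 5.35e-06). The probe set used for Cd8a moved by 0.29 (adjusted p = 0.0447), a call that 10 of the 12 single-array omissions ended (adjusted p up to 0.169), while its 4 other probe sets rose by 1.35 to 2.37. Apart from Cd8a, all 3 third-day arrays lay beyond all 3 untransduced arrays for every gene named in this paragraph.

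Most measured targets of the Notch pathway, which drives early T cell development, and 7 of 22 markers of the DN1 to DN3 stages fell at 3 days. Lmo2, a transcriptional cofactor of progenitors and of T cell leukemia, fell by 2.89 on the log2 scale (SE 0.19, adjusted p = 1.03e-07). Hes1, a direct Notch target, changed by -1.31 ± 0.10 (adjusted p = 3.17e-07), and Nrarp, a feedback inhibitor of Notch, by -1.24 ± 0.15 (adjusted p = 2.54e-05). Uaca changed by -2.09 ± 0.12 (adjusted p = 2.39e-08) and Notch1 itself by -0.62 ± 0.10 (adjusted p = 0.00038). Il2ra, the CD25 antigen by which DN stages are told apart, changed by -1.19 ± 0.15 (adjusted p = 4.11e-05) and did not pass the unmoderated 2-group test. Of 24 measured Notch targets 14 fell and 4 rose, also when adjusted over the list alone (median -0.36, camera adjusted p = 0.000791, and adjusted p = 0.266 with an estimated correlation). Of the 22 DN1 to DN3 stage markers 7 fell and 1 rose, again also when adjusted over the list alone. Their median was only -0.01, their mean -0.30, and camera placed them below the other genes (adjusted p = 0.0218, and adjusted p = 0.201 with an estimated correlation). Among the 25 T lineage transcription factors, 9 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.16, camera adjusted p = 0.0257, and adjusted p = 0.659 with an estimated correlation). Examples were Nfatc3 at 0.81 ± 0.08, Tcf3 (E2A) at 0.49 ± 0.07 and Lef1 at -0.48 ± 0.07. That list lost its call without untransduced array 2 (adjusted p = 0.0602), third-day array 2 (0.0911) or third-day array 3 (0.113). In every gene named in this paragraph the third-day and untransduced arrays did not overlap.

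**Figure D3:**
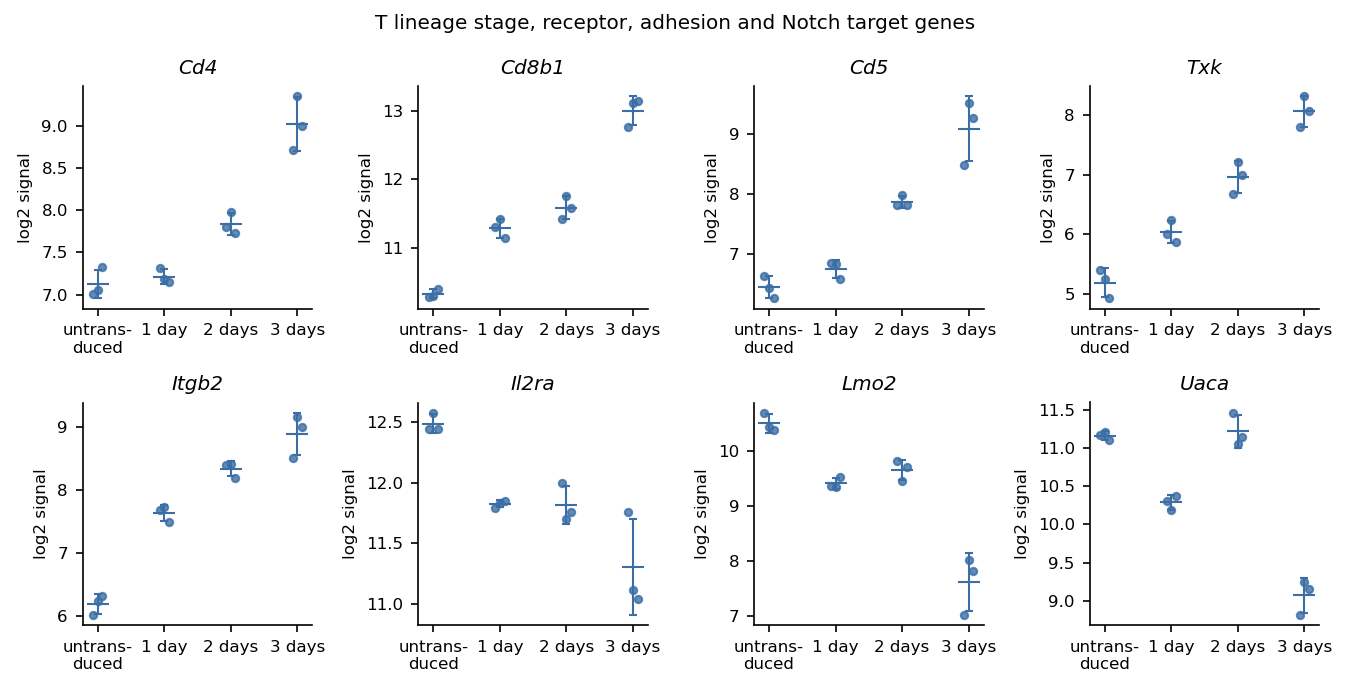
Log2 values of 8 genes of the T lineage on every array (points), by group, with the group mean (line) and SD (bar, n = 3). Cd4, Cd8b1, Cd5, Txk and Itgb2 reach their highest mean at 3 days, and Il2ra, Lmo2 and Uaca their lowest.

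The growth program moved the other way at 3 days. Of the 32 genes of the list on Myc and ribosome biogenesis 28 fell and 1 rose (30 and 1 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 4.71e-10, and adjusted p = 0.404 with an estimated correlation). The test fry did not call this list (adjusted p = 0.0787). Myc itself changed by -0.97 ± 0.09 (adjusted p = 2.81e-06) and Srm, the spermidine synthase, by -1.12 ± 0.26 (adjusted p = 0.0059). Lower too were the nucleolar proteins Gnl3 by -0.84 ± 0.16 (adjusted p = 0.00112) and Nolc1 by -0.84 ± 0.17 (adjusted p = 0.00227). Of these only Myc passed the unmoderated 2-group test. The single riser of the list was Mycn, a relative of Myc, at 6.40 ± 0.11 (adjusted p = 1.26e-13) in 1 of its 3 probe sets. Both other Mycn probe sets read below the median of all probe sets (4.87 and 3.23 in untransduced cells, against 5.71), with log2 changes of 0.14 (adjusted p = 0.399) and -0.19 (adjusted p = 0.198) at 3 days, and the mean over the 3 probe sets was 2.12. Across the array division the first of them was higher at 1 day (0.84 ± 0.10, adjusted p = 0.00012) and at 2 days (0.62 ± 0.10, adjusted p = 0.000268). The other was at -0.19 (adjusted p = 0.193) at 1 day and lower at 2 days (-0.32 ± 0.10, adjusted p = 0.0188). Cell cycle inhibitors and quiescence genes rose in 14 of 23 cases and fell in 1, also when adjusted over the list alone (median 0.53, camera adjusted p = 0.00017, and adjusted p = 0.404 with an estimated correlation). Cdkn2d (p19) rose by 1.36 ± 0.12 (adjusted p = 2.03e-06), the transcription factor Foxo1 by 1.06 ± 0.09 (adjusted p = 8e-07). Cdkn1a (p21) was the member that fell, at -0.44 ± 0.08 (adjusted p = 0.000616). The arrays of both groups were separate for each gene named here.

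Mitotic genes were higher rather than lower at 3 days. In the G2/M list 19 of 31 genes rose and none fell (22 rose adjusted over the list alone; median 0.33, camera adjusted p = 2.58e-07, and adjusted p = 0.404 with an estimated correlation). Among them were the mitotic factor Foxm1 (0.47 ± 0.08, adjusted p = 0.000542) and the centromere protein Cenpf (0.60 ± 0.11, adjusted p = 0.000813), both lost under the unmoderated 2-group test. The mitotic kinesin Kif14, outside the list, rose by 1.55 ± 0.08 (adjusted p = 6.85e-09). Of the 30 genes of DNA replication and G1/S, 3 rose, led by E2f2 at 1.46 ± 0.08 (adjusted p = 1.33e-08), and 8 fell (3 and 10 adjusted over the list alone; median -0.02, camera adjusted p = 0.299). Only 4 of the 28 replication dependent histones were measured, and 3 of them rose, also when adjusted over the list alone, with H1f4 at 1.15 ± 0.11 (list median 0.81, camera adjusted p = 0.00444, and adjusted p = 0.201 with an estimated correlation).

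camera also called the adhesion, NF-kB, p53, cholesterol and oxidative phosphorylation lists at 3 days. Itgb2, the shared beta chain of the leukocyte integrins, rose by 2.71 ± 0.14 (adjusted p = 1e-08). Of 24 adhesion and homing genes 11 rose and 3 fell, also when adjusted over the list alone (median 0.20, camera adjusted p = 0.000237, and adjusted p = 0.274 with an estimated correlation). In the list on NF-kB 5 of 19 genes rose and 1 fell, also when adjusted over the list alone (median 0.14, camera adjusted p = 0.0166, and adjusted p = 0.201 with an estimated correlation). Nfkbia, the inhibitor of NF-kB, rose there by 1.42 ± 0.10 (adjusted p = 2.13e-07). Of 23 p53 and apoptosis genes 6 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.20, camera adjusted p = 0.017, and adjusted p = 0.24 with an estimated correlation). The death gene Bbc3 (Puma) stood at 1.19 ± 0.12 (adjusted p = 6.77e-06). Cholesterol synthesis genes fell in 9 of 20 cases and rose in 1 (13 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 0.00444, and adjusted p = 0.711 with an estimated correlation), including Hmgcs1 (-0.78 ± 0.18, adjusted p = 0.00623). The cholesterol call was lost without third-day array 1 (adjusted p = 0.061). Of 29 oxidative phosphorylation genes 5 fell and 1 rose, also when adjusted over the list alone (median -0.11, camera adjusted p = 0.0257, and adjusted p = 0.772 with an estimated correlation). That call was lost without untransduced array 2 (0.0602), third-day array 2 (0.119) or third-day array 3 (0.247).

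camera called none of the remaining lists at 3 days. Of these, fry called the stress (adjusted p = 0.036), interferon (0.00195) and Bcl2 family (0.00581) lists. In the stress list of Atf4 and Xbp1 targets 5 of 26 genes rose and 12 fell (6 and 13 adjusted over the list alone; median -0.16, camera adjusted p = 0.242). In the interferon list 8 of 31 rose and 6 fell (9 and 8; camera adjusted p = 0.626), with Ifit2 at 2.50 ± 0.15 and Zbp1 at 1.46 ± 0.10. The counts were 1 up and 3 down of 22 glycolysis genes (0.242), 3 and 2 of 14 Bcl2 family genes (0.347) and 4 and 4 of 23 PI3K regulators (0.759), each with camera's adjusted p in parentheses. They were 6 and 5 of 26 Jak and Stat genes (0.77), 5 and 7 of 26 chromatin and NuRD genes (0.823), and 1 and 1 of the 5 Ikaros family genes (0.835). Adjusted over the list alone the Bcl2 family had 5 and 3, Jak and Stat genes 7 and 7 and chromatin genes 7 and 7. Markers of other cell types gave 1 up and 2 down of 21 B cell markers (0.626), 0 and 2 of 16 erythroid (0.626), and 1 and 0 of 20 NK cell markers (0.759). They gave 2 and 1 of 23 myeloid (0.77), 1 and 2 of 20 stem cell (0.823) and 1 and 1 of 22 fibroblast or packaging cell markers (0.855). Adjusted over the list alone the stem cell markers had 0 and 2, and the other lists the same counts. Myeloid Cebpb (1.52 ± 0.14, adjusted p = 1.5e-06), B cell Pou2af1 (1.09 ± 0.11, adjusted p = 4.44e-06) and Thy1 (0.71 ± 0.07), which the packaging cell list shares with T cells, were among the risers. Median, mean and camera's direction differed in sign at 3 days only for the Ikaros family, B cell, NK, stem cell and fibroblast lists, none of them called. In the other comparisons too, no list that camera called had such a difference.

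**Figure D4:**
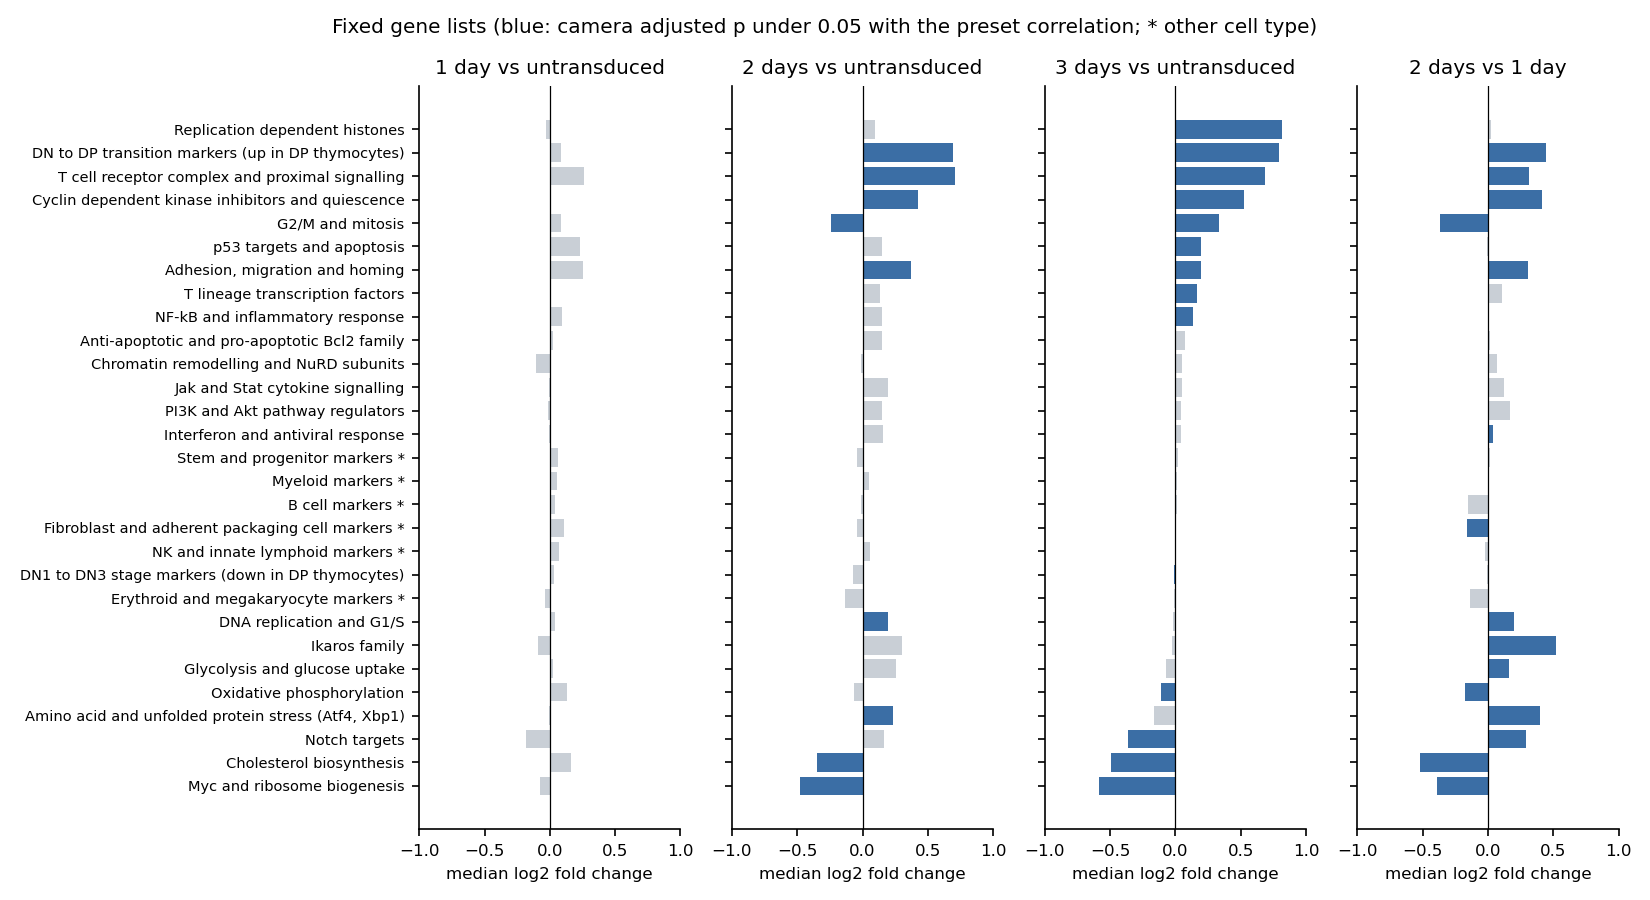
Median log2 change of each of the 29 gene lists in 4 comparisons, with lists called by camera with the preset correlation (adjusted p under 0.05) in blue. At 3 days the DN to DP list lies at 0.79 and the Myc list at -0.59, and no list was called with an estimated correlation.

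In total, 4512 of 18193 genes changed between untransduced cells and 3 days (2340 higher and 2172 lower, limma), with at least 2-fold changes in 288 and 242 genes. Of the called genes 51.9% were higher, or 48.7% after centring each array on its median. Third-day array 1 stood apart from its group, with correlations of 0.9945 and 0.9941 with arrays 2 and 3, against 0.9979 between those, and from 0.9909 to 0.9921 with the first-day arrays, against 0.9849 to 0.9877 for arrays 2 and 3. The SD of its deviations from the group mean was 0.181, where the other 11 arrays had 0.093 to 0.128. Without it limma called 5439 genes, without array 2 3432 and without array 3 3535. Large rises besides Mycn included Eci3 (4.80 ± 0.22, adjusted p = 2.43e-09), Glcci1 (3.98 ± 0.12, adjusted p = 1.72e-10) and the tubulin Tubb2b (3.72 ± 0.15, adjusted p = 9.02e-10). Large falls included Vwce (-3.13 ± 0.15, adjusted p = 4.56e-09), Rnf182 (-2.91 ± 0.15, adjusted p = 7.07e-09) and the sodium channel subunit Scn4b (-2.77 ± 0.12, adjusted p = 1.5e-09). Arrays of both groups did not overlap in 6273 genes (34.5%), where chance gives 10%. An unmoderated 2-group test called 1479 genes. camera called 14 of the 29 lists (9 up and 5 down) and, with an estimated correlation, none, when 5 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.201. The test fry, which tests whether a set moves one way on balance without comparing it with other genes, called 14, not all of them the same lists. It called the stress, interferon and Bcl2 family lists. It did not call the Myc (fry adjusted p = 0.0787), cholesterol (0.141) or oxidative phosphorylation (0.215) lists. Without third-day array 1, a setting chosen after the data were seen, estimated correlations called 4 lists: T cell receptor (adjusted p = 0.00826), DN to DP (0.0284), Myc (0.0254) and cell cycle inhibitor genes (0.0216). The T cell receptor and DN to DP lists share members, Cd4, Cd5 and Cd8b1 among them.

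Between the first and the second day, within the same side of the array division, genes of the amino acid and unfolded protein stress response rose. Ddit3 (Chop), the stress transcription factor, rose by 2.83 ± 0.13 (adjusted p = 1.59e-08; 1.61 as the mean over its probe sets), and the pseudokinase Trib3 by 2.62 ± 0.11 (adjusted p = 8.51e-09). Chac1, which degrades glutathione, rose by 2.55 ± 0.25 (adjusted p = 1.03e-05) and the cystine transporter Slc7a11 by 2.13 ± 0.21 (adjusted p = 1.15e-05). Nupr1, a stress-induced nuclear protein outside the list, rose by 4.39 ± 0.22 (adjusted p = 4.67e-08), from 6.46 to 10.85. Of the 26 stress genes 14 rose and 6 fell (15 and 6 adjusted over the list alone; median 0.40, camera adjusted p = 0.000162, and adjusted p = 0.11 with an estimated correlation). All 3 second-day arrays lay above all 3 first-day arrays for the genes named here, and the transferrin receptor's 3' to 5' difference was also largest in the second-day arrays. That of actin separated these days too (0.577 to 0.612 at 1 day and 0.684 to 0.779 at 2 days).

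**Figure D5:**
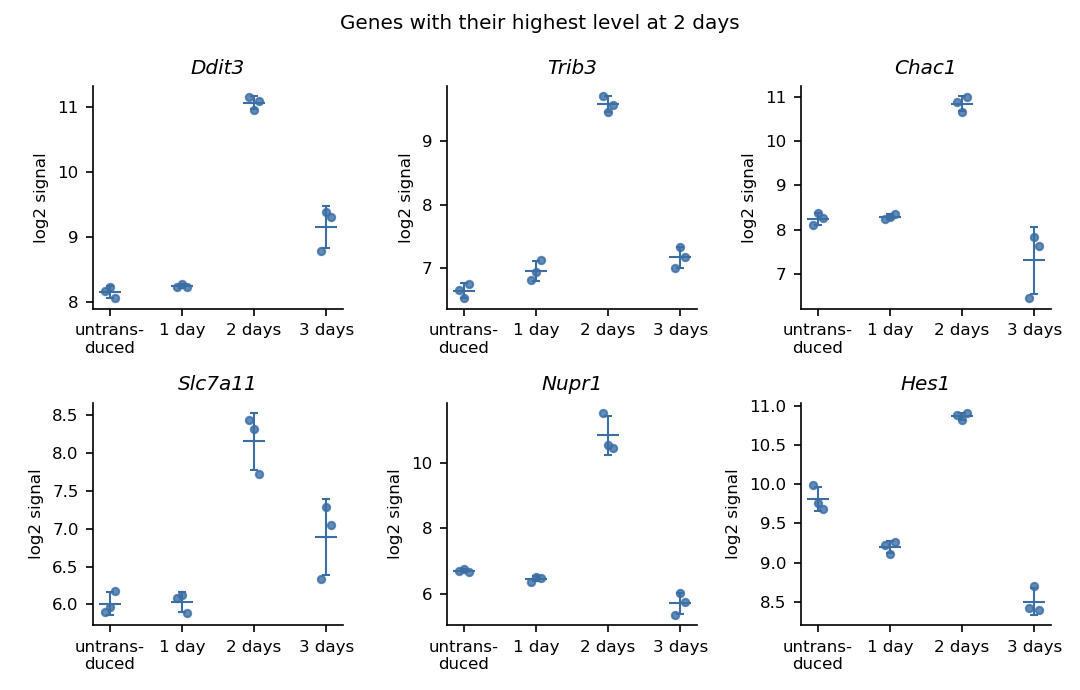
Log2 values of the stress genes Ddit3, Trib3, Chac1, Slc7a11 and Nupr1 and of the Notch target Hes1 on every array (points), by group, with the group mean (line) and SD (bar, n = 3). All 6 genes have their highest mean at 2 days.

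Notch targets and cell cycle genes also differed between the first 2 days. Hes1 rose by 1.67 ± 0.10 (adjusted p = 1.94e-07), Nrarp by 1.43 ± 0.15 (adjusted p = 1.44e-05) and Dtx1 by 0.85 ± 0.12 (adjusted p = 0.000203). In all, 12 of 24 Notch targets rose with none lower, also when adjusted over the list alone (median 0.29, camera adjusted p = 0.000154, and adjusted p = 0.377 with an estimated correlation). Of 25 DN to DP transition genes 17 rose and 4 fell (19 and 4 adjusted over the list alone; median 0.44, camera adjusted p = 2.9e-05, and adjusted p = 0.412 with an estimated correlation). Cd5 was among them at 1.12 ± 0.20 (adjusted p = 0.000812) and Rag2, a subunit of the receptor gene recombinase, at 0.69 ± 0.15 (adjusted p = 0.00423). Of 23 T cell receptor genes 12 rose and none fell (14 and 0 adjusted over the list alone; median 0.32, 0.000154 and, with an estimated correlation, adjusted p = 0.412). Klf4 (2.58 ± 0.19, adjusted p = 1.21e-06) and Txnip (2.52 ± 0.25, adjusted p = 1.18e-05) were among the cell cycle inhibitors and quiescence genes that rose. Of 23 such genes 13 rose and 1 fell, also when adjusted over the list alone (median 0.41, camera adjusted p = 2.9e-05, and adjusted p = 0.412 with an estimated correlation). In the G2/M list 17 of 31 genes fell and 3 rose (20 and 5 adjusted over the list alone; median -0.37, 2.9e-05 and, with an estimated correlation, adjusted p = 0.412). Kif23 was among them at -0.65 ± 0.10 (adjusted p = 0.000325). Myc genes fell in 13 of 32 cases and rose in 1 (18 and 1 adjusted over the list alone; median -0.39, 2.9e-05 and, with an estimated correlation, adjusted p = 0.512). Cholesterol genes fell in 14 of 20 and rose in 1, also when adjusted over the list alone (median -0.52, 0.000127 and, with an estimated correlation, adjusted p = 0.512).

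camera called 7 further lists between 1 and 2 days, each given here with its adjusted p and then its adjusted p with an estimated correlation. They were oxidative phosphorylation (8 lower of 29, median -0.18, 0.000162 and 0.543), DNA replication (12 higher and 2 lower of 30, median 0.20, 0.0042 and 0.412), adhesion (11 and 2 of 24, median 0.30, 0.00323 and 0.412) and the Ikaros family (4 higher of 5, median 0.52, 0.0197 and 0.412). The others were glycolysis (7 and 1 of 22, median 0.16, 0.0312 and 0.512), interferon (11 and 1 of 31, median 0.04, 0.0348 and 0.377) and fibroblast markers (0 and 2 of 22, median -0.16, 0.036 and 0.377). One riser of the Ikaros family was Ikzf1 in its brighter probe set (0.70), while its other probe set stood at -0.30 (adjusted p = 0.139). Adjusted over the list alone these counts were 14 and 2 for replication, 13 and 2 for adhesion, 8 and 1 for glycolysis, 0 and 0 for fibroblast markers and otherwise as given. Of these calls, 3 were lost without single arrays. Glycolysis was lost without first-day array 3 (0.0657) or second-day array 2 (0.0598) or 3 (0.0514), interferon without first-day array 3 (0.0626), and fibroblast markers without first-day array 1 (0.0722) or second-day array 3 (0.109). In total 4853 genes differed between the days (3084 higher and 1769 lower, limma; 297 and 24 at least 2-fold). Of these 63.5% were higher, or 75.6% after centring each array on its median. The arrays did not overlap in 8225 genes (45.2%). Of 29 lists camera called 15, fry 21, and camera with an estimated correlation 0, with 3 lists at an unadjusted p under 0.05. The Myc list was not among those that fry called (adjusted p = 0.0612). Markers of B cells (fry adjusted p = 0.0251), erythroid cells (0.0159) and fibroblasts or packaging cells (0.00632) were.

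One day after transduction, across the array division, some T cell genes were higher than in untransduced cells and others lower, and neither T cell list was called. The 3' to 5' difference of actin was also higher on every first-day array (0.599 on average, against 0.507). Of 23 T cell receptor genes 8 rose and 3 fell (10 and 3 adjusted over the list alone; median 0.26, camera adjusted p = 0.151, and adjusted p = 0.961 with an estimated correlation). Of 25 DN to DP genes 5 rose and 3 fell (8 and 6 adjusted over the list alone; median 0.09, camera adjusted p = 0.87, and adjusted p = 0.961 with an estimated correlation). Cd2 differed by 2.36 ± 0.29 (adjusted p = 0.000144), Cd8b1 by 0.96 ± 0.12 (adjusted p = 0.000121) and Sit1 by 0.72 ± 0.08 (adjusted p = 6.38e-05), while the receptor chain Cd3e was at -0.38 ± 0.09 (adjusted p = 0.0101). Cd4 (0.09 ± 0.14, adjusted p = 0.706) and Cd5 (0.31 ± 0.20, adjusted p = 0.313) did not pass. Outside the T cell lists, Itgb2 differed by 1.45 ± 0.14 (adjusted p = 3.02e-05), Tubb2b by 2.89 ± 0.15 (adjusted p = 4.27e-08) and Mycn by 5.94 ± 0.11 (adjusted p = 3.55e-13). Lower were Lmo2 (-1.09 ± 0.19, adjusted p = 0.00206), Hes1 (-0.61 ± 0.10, adjusted p = 0.00115), Notch1 (-0.61 ± 0.10, adjusted p = 0.0012) and Myc (-0.39 ± 0.09, adjusted p = 0.0112). For each of these that passed, the arrays of both groups were separate. limma called 3139 genes (2104 higher and 1035 lower), but 1892 without untransduced array 3, 1932 without first-day array 2 and 2016 without first-day array 3. Of the 3139 genes 67% were higher, or 74.2% of those called after centring each array on its median. At least 2-fold were 62 and 40 genes, and arrays did not overlap in 7489 genes (41.2%). camera called 0 of 29 lists, with 7 at an unadjusted p under 0.05, and 1 to 5 lists under 7 of the other settings. Of the lists, chromatin and NuRD genes had the lowest adjusted p (1 higher and 7 lower of 26, also when adjusted over the list alone; median -0.10, 0.0608, and 0.615 with an estimated correlation). Between 1 and 5 lists were called without untransduced array 2 (1) or 3 (2), first-day array 1 (2), second-day array 1 (2) or third-day array 1 (5) or 2 (1). fry called 7 lists, and camera with an estimated correlation 0, with 2 at an unadjusted p under 0.05. The lists of fry were NF-kB (adjusted p = 0.00294), p53 (0.0033), DN1 to DN3 (0.0241), chromatin (0.0336) and adhesion genes (0.0336). Markers of other cell types completed them, namely NK (0.0336) and myeloid cells (0.0343).

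At 2 days against untransduced cells, also across the division, more stress genes and T cell genes were higher than lower. The RNA control differed too, with a 3' to 5' difference of the transferrin receptor of 1.42 against 0.32 in untransduced cells, and of actin of 0.732 against 0.507. Nupr1 differed by 4.14 ± 0.22 (adjusted p = 3.41e-08), Trib3 by 2.93 ± 0.11 (adjusted p = 1.61e-09) and Chac1 by 2.61 ± 0.25 (adjusted p = 3.3e-06). Cd8b1 stood at 1.26 ± 0.12 (adjusted p = 2.14e-06), Txk at 1.77 ± 0.16 (adjusted p = 2.14e-06) and Cd5 at 1.43 ± 0.20 (adjusted p = 7.01e-05). The mitotic kinesin Kif20a was lower, at -1.39 ± 0.10 (adjusted p = 3.18e-07). All 3 second-day arrays lay beyond all 3 untransduced arrays for these genes. camera called 9 lists with the preset correlation and none with an estimated correlation, where the adjusted p was 0.512 for stress, 0.576 for cholesterol and 0.522 for the 7 others. Under the latter setting 1 list had an unadjusted p under 0.05, and fry called 18. Higher were T cell receptor genes (15 up and 1 down of 23, median 0.71, adjusted p = 5.3e-05), DN to DP genes (15 and 1 of 25, median 0.70, 0.000842), and cell cycle inhibitors (13 and 1 of 23, median 0.43, 0.00101). Higher too were adhesion (15 and 1 of 24, median 0.37, 0.00182), stress (13 and 6 of 26, median 0.24, 0.0111) and DNA replication genes (15 and 2 of 30, median 0.20, 0.0216). Lower were Myc genes (1 and 19 of 32, median -0.48, 1.8e-05), G2/M genes (4 and 16 of 31, median -0.24, 0.00023) and cholesterol genes (3 and 7 of 20, median -0.35, 0.0143). Adjusted over the list alone the counts were 16 and 1 (T cell receptor), 15 and 2 (DN to DP), 15 and 3 (replication), 1 and 23 (Myc), 5 and 16 (G2/M) and 3 and 9 (cholesterol), and otherwise as given. The cholesterol call was lost without untransduced array 1 (0.0586) or second-day array 1 (0.14), and the replication call without second-day array 2 (0.0598). By fry, neither the Myc nor the cholesterol list was called (adjusted p = 0.271 for both). Markers of myeloid cells (fry adjusted p = 0.00418), NK cells (0.00152) and fibroblasts or packaging cells (0.0194) were. limma called 6469 genes (4176 higher and 2293 lower; 506 and 54 at least 2-fold), and arrays did not overlap in 9004 (49.5%). By direction, 64.6% of the called genes were higher, or 79% after centring. Centring moved the median of all genes from 0.028 to 0.105 here and from -0.021 to -0.114 between 2 and 3 days.

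From the second to the third day, across the division, the Notch targets and stress genes stood lower and the mitotic genes higher. The 3' to 5' differences were lower too, with no overlap between arrays. That of the transferrin receptor was between 1.218 and 1.53 at 2 days and between 0.593 and 1.14 at 3 days, and that of actin between 0.684 and 0.779, then between 0.461 and 0.483. Hes1 changed by -2.37 ± 0.10 (adjusted p = 2.44e-09) and Nrarp by -2.43 ± 0.15 (adjusted p = 4.77e-08). Nupr1 changed by -5.14 ± 0.22 (adjusted p = 3.05e-09) and Chac1 by -3.54 ± 0.25 (adjusted p = 1.48e-07). Kif14 changed by 2.11 ± 0.08 (adjusted p = 1.28e-09), and Kif20a by 1.65 ± 0.10 (adjusted p = 4.8e-08). Cd8b1 changed by 1.42 ± 0.12 (adjusted p = 4.98e-07) and Cd4 by 1.18 ± 0.14 (adjusted p = 1.24e-05), with separate arrays in each of these genes. Of 31 G2/M genes 22 rose and 1 fell (median 0.54, camera adjusted p = 6.42e-12, and adjusted p = 0.391 with an estimated correlation). Notch targets fell in 17 of 24 cases and rose in 2 (median -0.43, 0.000376 and, with an estimated correlation, adjusted p = 0.391). Stress genes fell in 17 of 26 and rose in 3 (median -0.49, 0.000376 and, with an estimated correlation, adjusted p = 0.102). The 5 other calls, with adjusted p and then the adjusted p with an estimated correlation, were DN to DP genes (13 and 4 of 25, median 0.41, 0.00189 and 0.705), and replication (2 and 16 of 30, median -0.27, 0.00795 and 0.488). They also took in glycolysis (2 and 13 of 22, median -0.35, 0.00795 and 0.642), histones (3 and 0 of 4, median 0.64, 0.0188 and 0.297) and T cell receptor genes (11 and 6 of 23, median 0.24, 0.0273 and 0.904). Adjusted over the list alone the counts were 23 and 1 for G2/M, 4 and 17 for stress and 3 and 17 for replication genes, and otherwise as given. The T cell receptor call was lost without third-day array 2 (0.0819) or 3 (0.118). limma called 6846 genes (2625 higher and 4221 lower; 107 and 581 at least 2-fold), with arrays apart in 8360 (46%). Of the called genes 38.3% were higher, or 22.4% after centring. Without the dimmest 40% of genes camera called 4 lists rather than 8, and the unmoderated 2-group test called 3509 genes. With an estimated correlation camera called 0 lists, 3 had an unadjusted p under 0.05, and fry called 15. Among those of fry were markers of NK cells (adjusted p = 0.0141) and of fibroblasts or packaging cells (0.0151).

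Between the first and the third day, across the division, Cd4 (1.80 ± 0.14, adjusted p = 7.89e-07), Cd8b1 (1.71 ± 0.12, adjusted p = 2.64e-07), Cd5 (2.35 ± 0.20, adjusted p = 1.83e-06) and Ets2 (1.61 ± 0.09, adjusted p = 9.25e-08) were higher. Lmo2 (-1.79 ± 0.19, adjusted p = 1.43e-05) and Myc (-0.58 ± 0.09, adjusted p = 0.00029) were lower, and the arrays were separate in each of these genes. They were also separate in the 3' to 5' difference of actin (0.599 at 1 day and 0.475 at 3 days). camera called 11 lists, given with the adjusted p and then that with an estimated correlation. DN to DP genes (18 higher and 3 lower of 25, median 0.86, 6.43e-10 and 0.449), T cell receptor genes (15 and 0 of 23, median 0.49, 2.07e-07 and 0.449), cell cycle inhibitors (12 and 1 of 23, median 0.55, 3.78e-05 and 0.449) and G2/M genes (12 and 2 of 31, median 0.22, 2.13e-05 and 0.497) were higher. So were adhesion (10 and 3 of 24, median 0.23, 0.0019 and 0.449), histones (3 and 0 of 4, median 0.87, 0.00223 and 0.254), T lineage factors (9 and 4 of 25, median 0.13, 0.0275 and 0.594) and chromatin genes (12 and 5 of 26, median 0.22, 0.038 and 0.449). Lower were Myc genes (1 and 25 of 32, median -0.51, 2.53e-06 and 0.579), oxidative phosphorylation (0 and 16 of 29, median -0.24, 0.000227 and 0.641) and cholesterol genes (1 and 14 of 20, median -0.68, 0.000243 and 0.594). Adjusted over the list alone the counts were 18 and 4 (DN to DP), 15 and 1 (T cell receptor), 14 and 1 (inhibitors), 13 and 2 (G2/M), 11 and 3 (adhesion) and 13 and 6 (chromatin). For Myc they were 1 and 29, for oxidative phosphorylation 0 and 19, for cholesterol 1 and 17, and for the rest as given. The call on T lineage factors was lost without third-day array 2 (0.0723) or 3 (0.0654), and that on chromatin genes without first-day array 3 (0.0597) or third-day array 2 (0.0772). limma called 5893 genes (2373 higher and 3520 lower; 208 and 199 at least 2-fold), the unmoderated 2-group test 2249, and arrays did not overlap in 8004 (44%). Of the genes that limma called 40.3% were higher, or 31.8% after centring. With an estimated correlation camera called 0 lists, 1 had an unadjusted p under 0.05, and fry called 22. Among those of fry were markers of B cells (adjusted p = 0.0109) and of erythroid cells (0.0333).

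Genes called on more than 1 day moved the same way more often than the opposite way. Against untransduced cells 644 genes were higher and 218 lower on all 3 days, while 475 were higher at 2 days and lower at 3 days (498.6 if those calls were independent). Days 1 and 2 shared 1399 higher and 541 lower genes, where independent lists of those sizes would share 482.9 and 130.4. Both of these days lie across the array division from untransduced cells, so a shift between its sides could add to the genes they share. For days 1 and 3 the shared genes were 745 and 424 (270.6 and 123.6 if independent), and for days 2 and 3 they were 1387 and 569 (537.1 and 273.8). Across genes, which are not independent replicates, the log2 changes had Pearson's r of 0.536, 0.4 and 0.401 for these pairs (Spearman's rho 0.523, 0.255 and 0.299). Simulated unchanged groups that shared the 3 untransduced arrays gave r of 0.5, 0.5 and 0.502 and no shared call in any of 50 simulations. The simulations held independent, unchanged genes and no array division. Their lack of shared calls therefore sets no baseline for the counts above. The covariances were 0.0558, 0.0404 and 0.0614, against 0.006 in the simulations, so the differences were 0.0498, 0.0344 and 0.0554. The 3 untransduced arrays cannot be divided into parts of at least 2 arrays, and part of the excess may come from these shared controls. The comparisons of 2 days against 1 day and of 3 days against untransduced cells share no array, and there r was 0.161 (rho 0.149, covariance 0.0211, simulated r 0.001), with 951 shared rises (396.7 if independent) and 388 shared falls (211.2). Opposite calls there numbered 580 genes that rose from 1 to 2 days and were lower at 3 days than in untransduced cells (368.2 if independent) and 190 with the reverse order (227.5).

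A moderated F test over all 4 groups called 9630 of 18193 genes (52.9%), and 935 of these changed at least 2-fold against untransduced cells on at least 1 day.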

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

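Chosen after the results were seen were the tests of an array batch, of the Mycn probe sets, of culture or handling at 2 days and of splits of the arrays, while the estimated correlations and the means over probe sets were planned.

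Signal outside the gene comparisons, in the hybridization controls, was 1.322 higher on the log2 scale at 1 day and 1.247 higher at 2 days than in untransduced cells, so a batch of arrays is a candidate explanation for what differs across that division. As the whole cause, a batch that follows the division is argued against for the at least 2-fold changes at 1 day taken as sets, not for each gene. Batches that differ from group to group within a side cannot be told apart from the groups. The 62 genes at least 2-fold higher at 1 day had a median change of 1.486 (quartiles 0.56 and 2.27) at 3 days against untransduced cells, on one side of the division, and the 40 genes at least 2-fold lower a median of -1.182 (-1.953 and -0.64). Genes were also chosen without one untransduced array and read at 3 days against that array alone. The medians were then 1.279, 1.395 and 1.441 for higher and -1.126, -0.904 and -0.946 for lower genes. Their quartiles nearest 0 were 0.139, 0.387 and 0.556 for higher and -0.327, -0.472 and -0.408 for lower genes. No array stood in both differences, though the third-day arrays entered the estimate of the spread behind the choice. Single genes came back by 3 days, as a batch alone would give. Examples were Malat1 (13.083 in untransduced cells, 11.321 at 1 day and 13.352 at 3 days) and Trgv1 (6.273, 8.957 and 5.891). Such genes, part of each change across the division, and the many small ones stay open, because group and side cannot be told apart there. Ikaros, transduction and time in culture were not tested against one another.

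The signal of 1 Mycn probe set rose by 6.403 (SE 0.112) at 3 days against untransduced cells, within one side of the division. This argues against a batch that follows the division as the whole cause of the rise. The other 2 probe sets did not follow that probe set at 3 days, where their largest change was -0.19, but neither was brighter than the median of all probe sets (0 of 2). Whether probe sets this dim would show a rise of the whole Mycn transcript was not tested, so it stays open. Mycn was higher in one of them at 1 day (0.84) and 2 days (0.62) and lower in the other at 2 days (-0.32), across the division, so these values do not decide it either. Sequence shared between that probe set and the retrovirus was not tested, as neither sequence is used here.

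The 13 stress genes higher at 2 days than in untransduced cells had a median change of 1.169 (quartiles 0.787 and 2.126) against 1 day, on one side of the division. This argues against a batch that follows the division as the whole cause of their rise. A batch that separates the second-day from the first-day arrays could not be tested. Chosen without one second-day array and read in that array alone, such genes had medians of 1.469, 1.035 and 1.00. The whole list, with 14 genes higher and 6 lower than at 1 day, was not called with an estimated correlation (adjusted p = 0.11). Culture or handling of the second-day samples may also raise such genes, and it cannot be told apart from an effect of Ikaros because 0 untransduced arrays were taken at 2 days. The RNA control of the transferrin receptor was highest in the same arrays. That of actin also separated the days, from 0.577 to 0.612 at 1 day and from 0.684 to 0.779 at 2 days. RNA quality was not tested as a cause.

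Other results were called in opposite directions at 2 and at 3 days against untransduced cells, with the difference itself also called by limma or camera, across the array division. The RNA controls separated the arrays of these days as well, with mean 3' to 5' differences of 1.415 and 0.904 for the transferrin receptor and 0.732 and 0.475 for actin. The median of the G2/M list changed by 0.542 from 2 to 3 days, and its calls by camera were lost with an estimated correlation (adjusted p = 0.522 at 2 days, 0.404 at 3 days and 0.391 between them). Hes1 changed by -2.366 and Nrarp by -2.434 between these days. Nupr1 changed by -5.138 and Cdh2 by -3.271. Zfp948 changed by -4.342 and Fabp4 by -3.856, and both changes were smaller by over 1.5 times as means over probe sets. H3f3a changed by 2.441.

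Splits of the 6 arrays of a comparison are too few (10) for a share under 0.05. Only the real split, 1 of 10, called as many genes as 3139, 6469 and 4512 for 1, 2 and 3 days against untransduced cells, 4853 for 2 days against 1 day, 6846 for 3 days against 2 days and 5893 for 3 days against 1 day. The highest other split called 0 in each. For the F test over all groups, 1 of 100 splits of the 12 arrays, the real one, reached 9630 genes and the highest other 3306. This share argues against a chance division of the arrays for that count. It does not tell what made the groups differ. The arrays of a group may be technical repeats, and each group lies wholly on one side of the array division.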

How the results depend on the processing

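Chosen after the data were seen were the tests without shared probe sets, of the other Ikzf1 probe set, and with an estimated correlation and no third-day array 1. The cause was not tested for any change below unless fewer arrays, a stricter limit or fewer genes make it plain. Of 1734 results of named genes 1004 were called. Of these, 539 kept their call and direction under every setting that tested them. The call was lost somewhere for 461 and the direction turned somewhere for 21, some doing both. The stricter adjusted p, the 2-fold minimum and the test of every probe set were not applied to these results. Genes absent from a setting, such as the dimmest genes where those were left out, were not counted as lost there. Among the settings that were applied, 379 losses came from the unmoderated 2-group test, 102 from the mean over probe sets and 873 from leaving out 1 array. No called list was called in the opposite direction under the settings run, and a turn without a call was counted as a lost call.

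Counts of genes changed by over 1.5 times as follows. At 1 day (3139) array weights gave 4963 and every probe set 4773. An adjusted p under 0.01 gave 1331, 4210, 2943, 2936 and 3769 for 1, 2 and 3 days against untransduced cells, 2 days against 1 day and 3 days against 1 day. A 2-fold minimum gave 102, 560, 530, 321, 688 and 407 (the fifth being 3 days against 2 days), and 935 for the F test. The unmoderated 2-group test gave 1479, 3509 and 2249 for 3 days against untransduced cells, 2 days and 1 day. Without 1 array the counts ran from 1892 to 4262 at 1 day, 5168 to 7351 at 2 days, 3432 to 5439 at 3 days, 3430 to 5791 for 2 days against 1 day, 5725 to 7292 for 3 days against 2 days, 4458 to 6749 for 3 days against 1 day and 8758 to 10219 for F. The 1 day count was lowest without untransduced array 3 (1892).

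Lists called at 1 day (0 with all settings as chosen) were 1 with quantile normalization, 2 centred, 3 without the dimmest genes, 4 with an intensity trend, 3 with the mean over probe sets, 2 without shared probe sets and 5 with only the arrays of the 2 groups. Estimated correlations called 0 lists in all 6 comparisons. Without third-day array 1, whose deviations had an SD of 0.181 against 0.093 to 0.128 for the others, they called 1 at 2 days, 4 at 3 days, 2 for 2 days against 1 day, 0 for 3 days against 2 days and 4 for 3 days against 1 day. Without the dimmest genes 4 were called for 3 days against 2 days. Leaving out 1 array gave 0 to 5, 8 to 10, 12 to 14, 13 to 16, 7 to 10 and 10 to 12 lists.

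Ikzf1 was called at 1 day as the mean over probe sets (0.472) and in the other probe set (0.955), at 3 days likewise (0.553 and 1.236), and at 2 days not by the unmoderated 2-group test (0.691).

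The mean over probe sets turned Arpp21 at 1 day (-0.099), Btg1 (-0.109), Runx3 (0.003) and Nfatc2 (0.013) at 2 days, and Dleu2 at 3 days (-0.054). For 3 days against 2 days it turned Firre (-0.179), Bcl11a (-0.003), Pes1 (-0.208), Tyms (0.22), Hsd17b7 (0.051), Nfatc2 (-0.032), Igll1 (0.001) and Add2 (0.018), and for 3 days against 1 day Ikzf2 (0.034), Mycn (-0.078), Noc2l (0.128), Tyms (0.085) and Runx1 (0.111). Without shared probe sets Igll1 turned at 3 days (0.077), against 2 days (0.335) and against 1 day (0.368), and Trib2 (0.299) and Hsd17b7 (0.236) for 3 days against 2 days.

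The replicate numbers did not pair the arrays: of 18 correlations of deviations between same-numbered arrays 0 were over 0.1 (from -0.195 to 0.1), and 4 of 12 arrays correlated best with their own number. With the replicate block, counts were 2793, 6175, 4245, 4510, 6645, 5609 and 9284 for F, lists 0, 9, 14, 15, 8 and 11, and no Ikzf1 call changed. Signal over background limits dim probe sets such as those of Mycn.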

Other observations

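Many genes with large changes lie outside the lists. Glcci1, a gene induced by glucocorticoids, stood at 1.55 ± 0.12 at 1 day, 2.19 ± 0.12 at 2 days and 3.98 ± 0.12 at 3 days against untransduced cells (log2 ± SE, n = 3 arrays per group, limma adjusted p = 1.72e-10 at 3 days). Nsg2, a gene of neurons and of thymocytes, reached 3.17 ± 0.12 (adjusted p = 9.02e-10) and Gsn, which severs actin filaments, 3.26 ± 0.24 (adjusted p = 2.28e-07). The cell adhesion genes Mpzl2 (-2.80 ± 0.18, adjusted p = 5.17e-08) and Dsg1a (-2.94 ± 0.17) were lower at 3 days. Trgv1, a variable segment of the gamma chain locus, was higher at 1 day by 2.68 ± 0.13 (adjusted p = 3.21e-08) and changed by -3.07 ± 0.13 (adjusted p = 9.48e-09) from 1 to 3 days, across the array division. For each of these calls the arrays of the 2 groups compared did not overlap, which the rule that named these genes required on at least 1 day.

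Other large differences stood between the first and second day. Alox5ap, an activator of leukotriene synthesis, was higher than at 1 day by 3.18 ± 0.32 (limma adjusted p = 1.18e-05), the transcriptional regulator Id3 by 1.90 ± 0.27, and the insulin receptor substrate Irs1 by 1.39 with a later change of -2.45 from 2 to 3 days, across the array division. The heat shock protein Hspa8 (-1.61 ± 0.14, adjusted p = 4.13e-06) and Fbxo9 (-1.34 ± 0.07, adjusted p = 1.03e-07) were lower at 2 days than at 1 day, a comparison within one side of that division. Their arrays did not overlap, as the rule that named them required.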
